A study of Caenorhabditis elegans with 12 samples.

How the data were processed

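The series holds 12 ChIP-seq samples of whole worms, 3 in each of 4 groups given by the sample titles: wild-type input, wild-type precipitate, ETS-5 input and ETS-5 precipitate. Per the labels' protocols, frozen ground lysates were cross-linked with formaldehyde and sonicated, and an anti-GFP antibody was used. Replicate numbers come from the titles. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so the spread between them may be technical.

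The authors deposited 1 list of windows for each ETS-5 precipitate, with a chromosome, a start and an end per line and no header. Each window is 400 bp wide and its middle was taken as the summit. Bowtie2 and MACS2 are named in the submitters' processing notes, without versions or settings. The genome build, the peak threshold, the control used and the meaning of the line order are not given in the sources used here. Peaks called with or without the wild-type precipitate as control would give different lists, and which was done is open. The lists hold no scores, and 9 of the samples were not analysed here.

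Gene names and gene positions came from a RefSeq gene table of the assembly WBcel235. Since no build is stated for the windows, the fit of both coordinate systems was checked. The share of shared regions inside protein-coding genes was 35.4% with coordinates as deposited. It was 36.6% and 36.1% after shifting the regions by 100 bp to the left and right, 46.6% and 45.8% at 500 bp, and 63.8% and 64.4% at 5000 bp. The lowest value in steps of 10 bp lay at a shift of 40 bp, so the systems match to about 100 bp on average, while a larger local offset was not excluded. No coordinates of the gene table are printed, and region positions are those of the files, with starts counted from 1 on the assumption that the files count from 0.

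The gene table gives the ends of each gene but no strand, transcript start, exon or intron. The plan had been to assign regions from 2000 bp upstream to 500 bp downstream of a transcript start. In its place a gene counted as near a region when the region's centre lay from 2000 bp outside to 500 bp inside either end of the gene, so both 5' and 3' ends count. All 19971 protein-coding genes of the 6 nuclear chromosomes were used. Planned tests of ETS motifs and 6-base words needed a genome sequence and were not run. The planned comparison of peak scores was replaced by one of line order.

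Windows of the 3 lists were merged where they overlapped by at least 1 bp. A shared region holds a window of all 3 replicates, and its centre is the mean of its windows' centres. Overlap counts were checked against bedtools 2.31.1. Random expectations came from 1000 placements of the same number of windows on each chromosome (200 for alternatives), with chromosome length taken as the last position in the gene table or the lists. Gene lists were tested by the two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 21 lists. An alternative placed the regions at random 10000 times within the gene-end windows. Gene lists, tests and most of the other settings were fixed before the data were examined. Analyses used Python 3.11.15, scipy 1.17.1 and numpy 2.4.6.

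The genes to be named were fixed by rule. They are the genes at the 15 best-ranked shared regions, up to 15 best-ranked members of the BAG, serotonin, neuropeptide, guanylyl cyclase, ETS and homeobox lists, 12 genes named in advance whether near a region or not, and up to 3 members of each further list that passed. The rank was to be the peak score. With none given, the mean over replicates of the line number as a share of the list was used, a choice made after the lists were seen. The gene ceh-37, of the BAG neuron and homeobox lists, and the pan-neuronal genes beyond the best-ranked ones were named outside this rule, to complete counts.

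On simulated lists of the same sizes, 1000 of 1000 planted shared regions were recovered, and 3 shared regions appeared in lists placed at random. The planted windows were shifted too little to stop overlapping. Their recovery thus checks the merging step only and does not measure how many true sites are found. In 50 simulated gene sets over 19971 genes, a pan-neuronal list with 8 planted members was called each time, and 3.4% of tests of the other lists were called. Each planted member was given a region close enough to count as near. The calls of that list thus check the test step and do not measure how weak an excess would be found. Calls were made on the adjusted p, at a threshold of 0.05. The 34 calls of lists without planted members stood beside 50 of the planted list. False calls were thus a larger part of all calls than the adjustment aims for. Alternatives were another overlap of 100 bp, regions of at least 2 replicates, each replicate left out, the first 50% of each list's lines, other gene windows and shifted coordinates. The first 50% of lines, the shifted coordinates and the gene-end window in place of the transcript start were chosen after the lists were seen.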

Results

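The series profiled genome binding in the nematode Caenorhabditis elegans by chromatin immunoprecipitation and sequencing (ChIP-seq). ETS-5 is a transcription factor of the ETS family, known from earlier work for its role in the BAG neurons, a pair of head sensory neurons that detect respiratory gases. Whole-worm extracts of a strain carrying ETS-5 fused to green fluorescent protein, and of the wild-type strain N2, were precipitated with an antibody against the fluorescent tag. The 12 samples form 4 groups of 3, namely an input and a precipitate for each strain. Window lists for the 3 ETS-5 precipitates were used here. The wild-type precipitates and all inputs were not analysed here, so no difference between strains or from input was computed. Whether the authors called the windows against any of them is not given in the sources used here. The question that could be addressed was where the ETS-5 precipitates placed their windows, which genes lie near them, and how far the 3 replicates agreed.

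Replicate 1 held 3811 windows, replicate 2 held 2915 and replicate 3 held 3697, which gives 3474 ± 488 windows (SD, n = 3). Every window was 400 bp wide. The lists carry no read counts, heights or p-values, so the sequencing depth behind each window is unknown. The X chromosome held 21.01% ± 1.53 of the windows (SD, n = 3), with 22.4% in replicate 1, 21.3% in replicate 2 and 19.3% in replicate 3. The chromosome makes up 17.7% of the length of the 6 nuclear chromosomes, each taken up to its last position in the gene table or the lists. The exact 95% binomial interval excluded that share in each replicate, with lower bounds of 21.04%, 19.9% and 18.1%. Chromosome III held 15.9% ± 0.949 of the windows (SD, n = 3) against 13.7% of the length, and chromosome I held 16.6% ± 0.713 against 15.03%. Chromosome V held 16.2% ± 0.471 of the windows (SD, n = 3) against 20.9% of the length, and chromosome IV held 14.9% ± 0.373 against 17.4%. These intervals cover counting error only and treat windows as independent.

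The replicates placed many of their windows at the same sites. Of the windows of replicate 2, 85.9% overlapped a window of replicate 1 by at least 1 bp, and 67.2% overlapped one of replicate 3. Of the windows of replicate 3, 61.5% overlapped one of replicate 1. Random placement of one list on the same chromosomes gave 3.05%, 2.96% and 3.06% on average for these pairs, and 4.15% at most. The one-sided permutation p was 0.001 for each pair, the smallest that 1000 placements can give. Where windows overlapped, their centres lay a median of 22 bp apart between replicates 1 and 2, 33 bp between replicates 1 and 3 and 32 bp between replicates 2 and 3.

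Merging the 3 lists gave 5455 regions. Of these, 1788 held a window of all 3 replicates and are called shared regions below. Random placement of all 3 lists gave 3.92 such regions on average and 11 at most (one-sided permutation p = 0.001, the smallest possible). Replicates 1 and 2 alone shared a further 718 regions, replicates 1 and 3 shared 488, and replicates 2 and 3 shared 178. Regions seen once numbered 814 in replicate 1, 229 in replicate 2 and 1240 in replicate 3.

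The order of the lines in each list went with recovery in the other lists. In the first 10% of its lines, 93.2% of the windows of replicate 1, 95.9% of those of replicate 2 and 70.3% of those of replicate 3 overlapped both other lists. In the last 10% the shares were 12.3%, 29.9% and 18.97%. Across windows that overlapped, Spearman's rho of line number was 0.81 between replicates 1 and 2, 0.39 between replicates 1 and 3, and 0.37 between replicates 2 and 3. These are correlations across windows, which are not independent replicates. No file says what the order stands for. It is used below to choose which regions to name, to give their place in each list and to take the first part of each list in some comparisons.

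**Figure D1:**
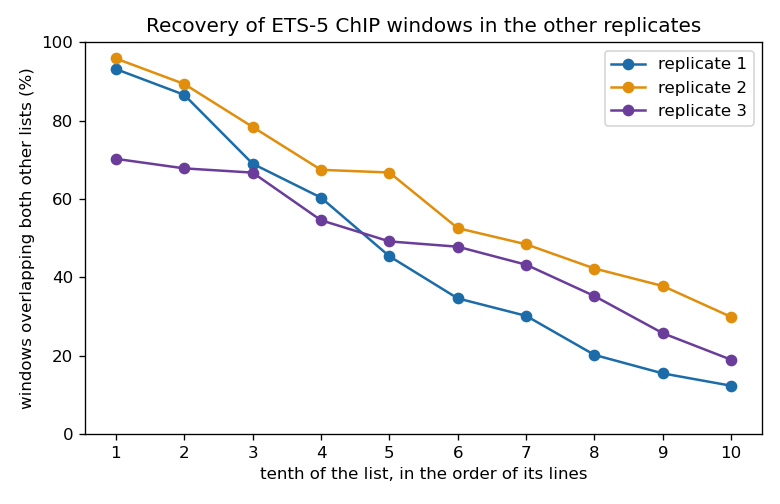
Share of windows (percent, vertical axis) that overlap a window of both other replicates by at least 1 bp, for each successive 10% of a list in the order of its lines (horizontal axis); 1 line per replicate. The share falls from 93.2%, 95.9% and 70.3% in the first 10% of replicates 1, 2 and 3 to 12.3%, 29.9% and 18.97% in the last.

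The gene ets-5 itself led every list. A region on chromosome X from 5084088 to 5084488, counted from 1 in the coordinates of the files, whose build is not given in the sources used here, was the first line in all 3 replicates and lay inside ets-5 near one end of the gene. A further shared region inside ets-5, at 5081167 to 5081594, stood at line 2 in replicate 1, line 3 in replicate 2 and line 5 in replicate 3. The third by mean rank was a region on chromosome X at 15735649 to 15736078, at line 3, 4 and 3. It lay near lin-15A, a gene of vulval development, and near srg-64, a gene of a chemoreceptor family. The next were a region on chromosome IV at 11071023 to 11071424, with ttr-17 as its nearest protein-coding gene, and a region on chromosome II at 14569226 to 14569635, with madf-5 as its nearest. Neither lay inside a protein-coding gene or within 2000 bp of one.

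Others among the 15 best-ranked shared regions lay near eor-1 and R11E3.1, near the histone genes his-35, his-37 and his-41 with C50F4.6 and nstp-10, and near lgc-26, clec-80, fath-1 and F53F8.5. A region inside F53F8.6 was the one near F53F8.5. One lay inside cnp-2. The remaining ones lay farther than 2000 bp from any protein-coding gene, with Y102F5A.1, Y7A5A.7 and Y119C1B.3 as their nearest. Histone genes occur in near-identical copies, so reads can be shared between them, and windows there are uncertain.

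Shared regions lay mostly outside protein-coding genes, the only genes counted in this comparison and the next. Of the 1788 regions, 64.6% had their centre outside every protein-coding gene, against 38.0% for random placement on the same chromosomes. The share inside genes was 35.4% for shared regions, and over the full lists it was 36.6% ± 2.55 (SD, n = 3). No random placement of the shared regions gave less than 58.3% inside genes (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The excess outside genes held at each distance from the nearest gene. Within 500 bp lay 20.9% of shared regions against 11.7% at random, from 500 to 1000 bp 10.7% against 6.39%, from 1000 to 2000 bp 12.98% against 7.62%, and beyond 2000 bp 19.97% against 12.3%. Each of these had a one-sided permutation p of 0.001.

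A window from 2000 bp outside to 500 bp inside either end of a gene, chosen after the lists were seen, was the measure of lying near a gene. By that measure 55.43% of shared regions lay near at least 1 gene, against 59.2% at random on average and 55.48% in the lowest of 1000 placements. The share thus lay below every placement, and the one-sided permutation test for a higher share gave p = 1. With 1000 bp outside and 0 bp inside, the direction turned, with 36.5% against 32.1% at random (one-sided permutation p = 0.005, the smallest that 200 placements can give). The wider measure takes in up to 500 bp of gene interior at each end. Inside genes lay 35.4% of regions against 62.0% at random, while each distance outside held more than random. The low share of the wider measure is thus no sign that regions avoid the sequence beside genes.

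Genes that all neurons use were found near shared regions more often than other genes. Of 21 pan-neuronal genes, 11 lay near a shared region, which is 52.4% against 7.39% of all other protein-coding genes (odds ratio 13.8, Fisher's exact test, adjusted p = 4.55e-07 over 21 lists). The 11 were maco-1, snb-1, rgef-1, egl-21, unc-64, ehs-1, unc-33, unc-10, unc-11, unc-104 and egl-3. The gene snb-1 encodes synaptobrevin and unc-64 encodes syntaxin, both parts of the synaptic vesicle fusion machinery. The genes egl-3 and egl-21 encode enzymes that process neuropeptide precursors, and unc-104 encodes a kinesin that carries synaptic vesicles. The best placed was maco-1, at line 8, 7 and 306 of replicates 1 to 3. Then came snb-1, at line 182, 240 and 61, and rgef-1, at line 295, 226 and 1034. In the full lists, 68.3% ± 7.27 of pan-neuronal genes lay near a window (SD, n = 3), against 13.6% ± 1.75 of all protein-coding genes.

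Ribosomal protein genes were also found near shared regions more often than other genes, with 25 of 78 (32.1% against 7.34%, odds ratio 5.96, Fisher's exact test, adjusted p = 1.90e-09). The best placed were rps-28, rpl-7A and rpl-11.2. The share in the full lists was 54.3% ± 12.1 (SD, n = 3), and it was highest in replicate 3 with 53 genes, against 39 in replicate 1 and 35 in replicate 2. Replicate 3 also placed more windows at small RNA genes. When each region was given only to its nearest gene, 11 ribosomal protein genes were counted and the call was lost (odds ratio 2.06, Fisher's exact test, adjusted p = 0.194).

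Heat shock genes came to 9 of 24 (37.5% against 7.40%, odds ratio 7.51, Fisher's exact test, adjusted p = 0.000167). These 9 genes lay near only 5 regions, and 6 of them belong to the small heat shock genes of the hsp-16 family. The best placed were hsp-16.48, hsp-16.49 and hsp-16.11, which share a cluster on chromosome V. The hsp-16 genes include near-identical copies, so windows there are uncertain. The call was lost with the nearest gene alone (odds ratio 3.29, adjusted p = 0.152) and in the first 50% of each list's lines (odds ratio 2.59, adjusted p = 0.685), both by Fisher's exact test.

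Chemoreceptor genes, a large group of families of G protein-coupled receptors, lay near shared regions less often than other genes. Of 1308 genes, 23 did (1.76% against 7.83%, odds ratio 0.211, Fisher's exact test, adjusted p = 7.92e-20). The best placed of these were srg-64, which shares its region with lin-15A, then str-221 and srg-69. In the full lists the share was 3.39% ± 0.842 (SD, n = 3).

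**Figure D2:**
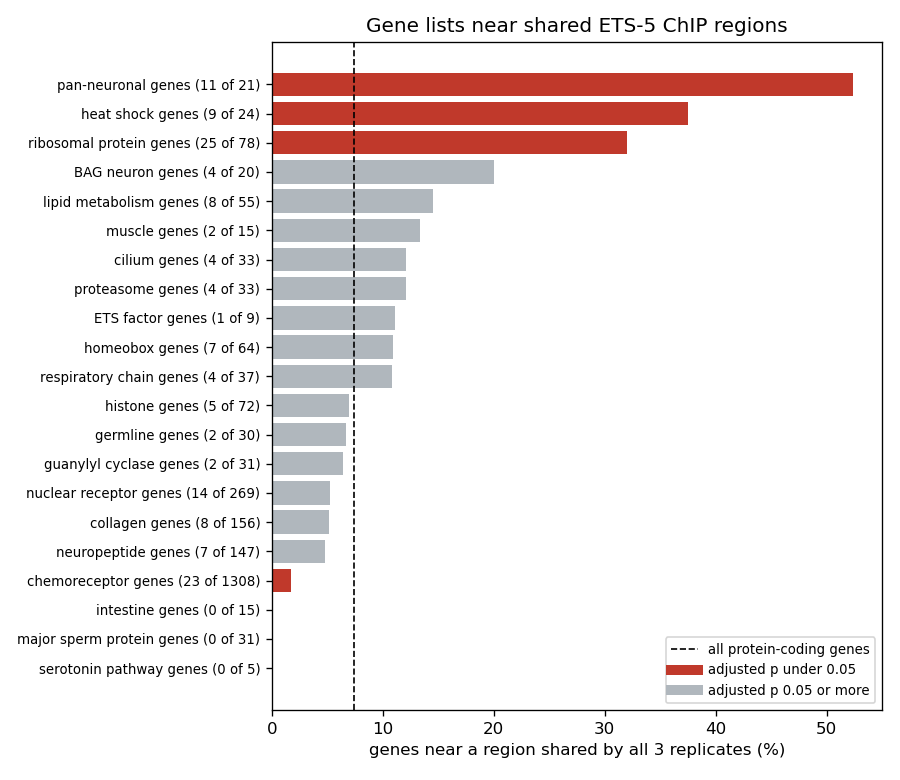
Share of each fixed gene list (percent, horizontal axis) near a region shared by all 3 replicates, with the number near and the list size beside each name; red bars passed Fisher's exact test after adjustment and the dashed line marks all protein-coding genes. Of the lists that passed, pan-neuronal genes (52.4%), heat shock genes (37.5%) and ribosomal protein genes (32.1%) stand above the line, and chemoreceptor genes (1.76%) below it. Lists that did not pass lie on both sides of the line.

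The list of BAG neuron genes did not pass the test. Of its 20 members, 4 lay near a shared region (odds ratio 3.12, Fisher's exact test, p = 0.0566 and adjusted p = 0.222). One of the 4 was ets-5, the tagged gene, whose windows cannot be told apart from extra copies here. The test was not repeated without it. The others were gcy-33, a soluble guanylyl cyclase gene, tol-1, the Toll-like receptor gene, and ceh-37, a homeobox gene. The window near gcy-33 stood at line 2809, 1766 and 875 of replicates 1 to 3, and that near tol-1 at line 809, 1310 and 2838. In the full lists the share of BAG neuron genes was 21.7% ± 2.89 (SD, n = 3).

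Several genes known for BAG function had no window in any of the 3 lists, either inside the gene or within 2000 bp of it. These were gcy-9 and gcy-31, both guanylyl cyclase genes, the neuropeptide genes flp-13 and flp-19, the insulin gene ins-1, and the transcription factor genes nhr-6 and egl-13. The neuropeptide gene flp-17 had a window in replicate 3 alone, at line 1586. A missing window means only that the authors' list holds none there, since the depth and the threshold are unknown. Sites farther than 2000 bp from a gene were not assigned to it.

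Other lists tied to neurons did not pass either. Serotonin pathway genes had 0 of 5 near a shared region. Among them tph-1, the gene of the enzyme that makes serotonin, had a window in replicate 1 at line 3206 and in replicate 2 at line 2181 but none in replicate 3. Neuropeptide genes had 7 of 147 near a shared region (Fisher's exact test, adjusted p = 0.498), namely nlp-66, ins-13, ins-37, ins-17, nlp-53, ins-39 and nlp-40. Guanylyl cyclase genes had 2 of 31, gcy-5 and gcy-33. Without replicate 3, guanylyl cyclase genes had 4 and serotonin pathway genes 2, neither list passing. Homeobox genes had 7 of 64 (Fisher's exact test, adjusted p = 0.498), with ceh-89, ceh-20, ceh-39 and ceh-5 the best placed. Cilium genes had 4 of 33 (Fisher's exact test, adjusted p = 0.498) and the ETS factor list had ets-5 alone among 9.

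The lists chosen for contrast, other than those above, did not pass the test. Against 7.44% of all genes, muscle genes had 2 of 15 near a shared region, germline genes 2 of 30, collagen genes 8 of 156, histone genes 5 of 72 and nuclear receptor genes 14 of 269. Proteasome genes had 4 of 33, respiratory chain genes 4 of 37 and lipid metabolism genes 8 of 55. Intestine genes had 0 of 15 and major sperm protein genes 0 of 31. Without replicate 2 muscle genes had 4 (odds ratio 3.60 against 1.92), and histone genes had 10 (1.60 against 0.929). Without replicate 1 respiratory chain genes had 7 (2.58 against 1.51) and proteasome genes 3 (1.10 against 1.72). Without replicate 3 germline genes had 1 (0.317 against 0.889) and major sperm protein genes 1 (0.306 against 0). None of these passed Fisher's exact test. With all 3 replicates the lowest adjusted p among these lists was 0.222, for lipid metabolism genes. In all, 1485 of 19971 protein-coding genes (7.44%) lay near a shared region, and 4 of the 21 lists passed, 3 above and 1 below the other genes. Neighbouring genes can share a region, so genes are not fully independent in these tests. In the simulations the adjusted test made more false calls than its threshold aims for.

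The replicates differed at small RNA genes. Within 200 bp of a transfer RNA gene lay 65 windows of replicate 3 (1.76%, exact 95% binomial interval 1.36% to 2.24%), against 15 of replicate 1 (0.394%, 0.220% to 0.648%) and 9 of replicate 2 (0.309%, 0.141% to 0.585%). Random placement gave 10.4, 11.2 and 8.54 windows on average for replicates 3, 1 and 2. By Fisher's exact test the odds were 4.53 times higher in replicate 3 than in replicate 1 and 5.78 times higher than in replicate 2 (adjusted p = 2.54e-08 for each). At small nuclear RNA genes, which belong to the splicing machinery, replicate 3 had 28 windows against 10 and 5 (Fisher's exact test, adjusted p = 0.00791 and 0.00215). Random placement gave 2.26, 2.29 and 1.76 such windows on average for replicates 3, 1 and 2, and 8 at most. Replicate 1 thus also lay above every placement there. At small nucleolar RNA genes replicate 3 had 28 against 10 and 11 (Fisher's exact test, adjusted p = 0.00791 and 0.0890). These tests compare 3 libraries of 1 group, not conditions. Only 5 shared regions lay at a transfer RNA gene, and 7 lay at a small nuclear RNA gene.

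**Figure D3:**
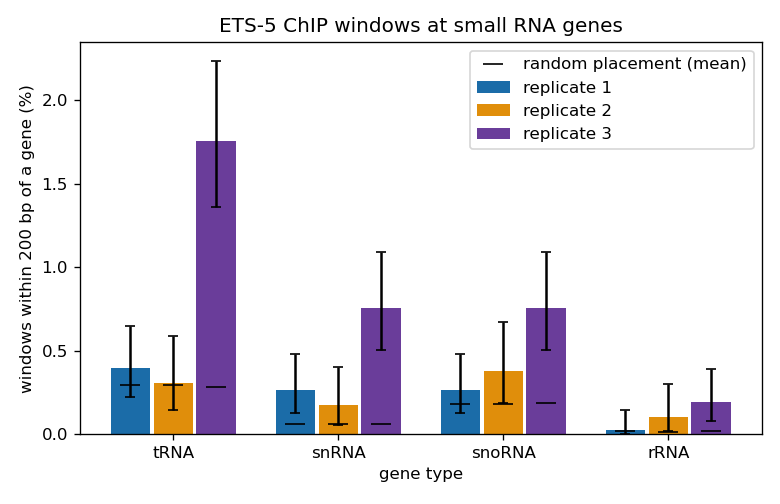
Share of each replicate's windows (percent, vertical axis) whose centre lies within 200 bp of a gene of each small RNA type (horizontal axis), with exact 95% binomial intervals; short black lines mark the mean of random placement. Replicate 3 stands at 1.76% for transfer RNA genes, against 0.394% and 0.309% in replicates 1 and 2.

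The density of windows around the tagged gene was compared with other stretches of chromosome X. Within 25000 bp on either side of ets-5 lay 5, 5 and 4 windows of replicates 1 to 3 (4.67 ± 0.577, SD, n = 3), against a mean of 2.27 for stretches of that length. Of these windows, 2, 3 and 3 lay inside ets-5 or within 2000 bp of it, the leading ones among them. The count is thus not one of the surroundings alone. Over the 3 replicates together, 91.5% of those stretches held fewer windows. Around unc-119, a common transformation marker gene, lay 3, 3 and 1 windows (2.33 ± 1.15, SD, n = 3), and 57.5% of equal stretches of chromosome III held fewer over the 3 replicates together. A shared region lay inside or within 2000 bp of unc-119.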

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

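The settings that used the first 50% of each list's lines or shifted coordinates were added only after the data were seen. No paired analysis was possible because window lists of only 1 of the 4 groups were used here. The ETS motif, 6-base word and peak score analyses were not run, and depth could not be judged from windows without counts. Pan-neuronal and chemoreceptor calls kept their direction and significance under all 14 alternatives, with adjusted p of at most 0.00834 and 0.0014, and BAG neuron genes passed under none (lowest adjusted p 0.197). Ribosomal protein genes kept their call under 13 of 14 and heat shock genes under 12 of 14. These settings are not independent, since many kept nearly all genes near a shared region. The share kept was 97.6% with an overlap of 100 bp, 99.1% to 99.9% with 1 replicate left out and 89.5% after shifts of 500 bp. Pairwise overlap averaged over the pairs stayed between 66.8% and 71.5% and above random under all 3 alternatives. Shared regions numbered 3172 with at least 2 replicates and 770 in the first 50% of the lines. The genes near them numbered 2487 and 679, and 850 with the window of 1000 bp outside and 0 bp inside, which also turned the share of regions near genes from below to above random (36.5%). With the nearest gene alone 2 lists passed in place of 4. The ets-5 stretch of 50000 bp on either side had more windows than 98.8% of stretches. Nuclear receptor genes passed as less frequent with at least 2 replicates (odds ratio 0.561, Fisher's exact test, adjusted p = 0.0490). The turn of the share near genes goes with how much gene interior each window takes in. The cause of the other changes was not tested.

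Some lists crossed an odds ratio of 1, passing the test on neither side. With 1000 bp outside and 0 bp inside these were ETS factor (0), histone (1.32) and muscle genes (0). With the nearest gene they were cilium (0.805), guanylyl cyclase (1.85), proteasome (0) and lipid metabolism genes (0.979). Guanylyl cyclase genes reached 1.90 with whole gene spans, and proteasome genes 0.824 with a 100 bp overlap. With at least 2 replicates the values were 4.69 for serotonin pathway, 0.970 for cilium, 1.04 for guanylyl cyclase, 0.879 for ETS factor and 1.13 for histone genes. In the first 50% of the lines they were 0.916 for homeobox and 2.13 for histone genes. After a shift of 500 bp to the left they were 1.33 for guanylyl cyclase, 0 for ETS factor and 0.889 for muscle genes. Histone genes gave a ratio of 1.16 to random placement within gene-end windows. Leaving out 1 replicate in turn gave 0 to 6.13 for serotonin pathway, 0.682 to 1.36 for guanylyl cyclase, 0.685 to 1.60 for histone and 0.317 to 1.10 for germline genes, the top values coming without replicate 3 for the first pair of lists and without replicate 2 for the others.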

Other observations

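The comparison of gene families, from which the acr genes were picked, the tests of transfer RNA windows, the density around lin-15A and the bound of 95% for ets-5 were chosen only after the result was seen.

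Gene families by name were compared in the same way, over 183 families with at least 10 members, of which 8 passed Fisher's exact test after adjustment. Random placements within gene-end windows, adjusted over the same 183 families, left 3 that passed, namely rpl, rps and unc (permutation test, adjusted p = 0.0122 for each). Genes of nicotinic acetylcholine receptor subunits (acr) had 7 of 21 members near a shared region (odds ratio 6.25, Fisher's exact test, adjusted p = 0.0173), with acr-18, acr-10 and acr-12 the best placed. The unc genes, named for uncoordinated movement and many of them active in neurons, had 24 of 94 (odds ratio 4.32, Fisher's exact test, adjusted p = 1.14e-05), led by unc-76, unc-115 and unc-70, and 5 of the 24 also belong to the pan-neuronal list. The lin genes, named for cell lineage defects, had 10 of 47 (odds ratio 3.38, Fisher's exact test, adjusted p = 0.0468), led by lin-15A and lin-41. Without lin-15A, whose window is weighed separately, the family had 9 of 46 and did not pass (odds ratio 3.04, Fisher's exact test, adjusted p = 0.0915). Below the other genes lay the chemoreceptor families srh, with 3 of 220 (odds ratio 0.170, Fisher's exact test, adjusted p = 0.00291), and srx, with 0 of 101 (Fisher's exact test, adjusted p = 0.0217). The remaining families that passed were rpl, rps and hsp, which the fixed lists already held. These example genes were named after their values were seen.

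The windows at the ends of some genes cover more sequence than those of others, which could by itself bring a list near more regions. Over 10000 random placements within gene-end windows, the most pan-neuronal genes reached was 8 against 11 observed, and the most ribosomal protein genes was 17 against 25. The fewest chemoreceptor genes was 45 against 23. Total window width alone thus did not account for these 3 lists. The placements spread evenly over gene interior and the sequence outside, while shared regions favoured the outside. How much sequence outside genes each window holds was not tested. Placements reached up to 10 heat shock genes against 9 observed, so width stays open for them by the bound that no placement reach the observed number. Few placements did so, and by its p-value the list passed (permutation test, adjusted p = 0.0126 over the 21 lists). The acr genes did not pass once adjusted over the families they were picked from (permutation test, adjusted p = 0.11), so width stays open for them too. Accessible chromatin and peaks that any antibody would give were not tested, since wild-type precipitates and inputs were not analysed here.

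Windows at ets-5 and near lin-15A stood among the first 5 lines of all 3 lists. Extra copies of the tagged gene, inserted with a marker gene, could raise coverage over both without binding. Stretches of chromosome X with fewer windows made up 91.49% for 25000 bp on either side of ets-5, 95.3% for 10000 bp and 98.8% for 50000 bp. These counts include the windows in or within 2000 bp of ets-5, which prompted the test and numbered 2, 3 and 3 in replicates 1 to 3. Within 10000 bp lay 3, 4 and 3 in all, so that width says little about a broad block. Within 50000 bp lay 10, 12 and 12, most of them elsewhere. The widths gave different answers for ets-5 against the bound of 95% set for the test. For lin-15A, stretches with fewer windows made up 75.06% at 25000 bp, 86.8% at 10000 bp and 64.2% at 50000 bp. All lay under that bound over the 3 replicates together. In replicate 3 alone the value at 10000 bp was 95.8%, against 70.1% and 49.5% in replicates 1 and 2. Over the replicates together, windows did not crowd a broad stretch there, while extra copies of a short marker stay open. Binding of ETS-5 to its own gene, extra copies and a co-inserted marker cannot be told apart here, since windows without heights do not show coverage and how the tagged gene was inserted is not given in the sources used here.

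Replicate 3 held 65 windows at transfer RNA genes. List length and random placement did not account for them, since 60 lay among its first 2915 lines, against 9 in each other replicate, and random placement of its full list reached 23 at most. A preference for heavily transcribed genes in that library may play a part and stays open. Ribosomal protein genes near a window of replicate 3 alone numbered 18 against 4 for replicate 1 alone and 22 against 4 for replicate 2 alone (Fisher's exact test, adjusted p = 0.0469 and 0.142), histone genes, whose near-identical copies make windows uncertain, 20 against 0 and 25 against 0 (adjusted p = 0.000106 and 0.000412), proteasome genes 8 against 1 in both cases (adjusted p = 0.142 and 0.328), and pan-neuronal genes 2 against 5 and 2 against 3 (adjusted p = 0.196 and 0.335). Only histone genes passed against both other replicates. Neighbouring histone genes can share a window, as with the 5 that lay near only 2 shared regions. The test counts each gene as independent, so its p-values for histone genes may be too small. No biological explanation was tested, since the replicates belong to 1 group.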
